A study of Mesocricetus auratus with 6 samples.

How the data were processed

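RNA of the uterus of pregnant golden hamsters (Mesocricetus auratus) on day 5 of pregnancy was measured on an Affymetrix mouse expression array, with 3 arrays of implantation sites and 3 arrays of the uterine segments between them, called interimplantation sites. Per the labels' protocols, total RNA was extracted with Trizol. Per the series' design text, the RNA sets came from 3 different animals, so the arrays of a group are biological replicates, and the same RNA was also hybridised to a human array, which was not analysed here. Whether an implantation and an interimplantation array of the same number came from the same animal is not given in the sources used here.

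The deposited table held 1 value per probe set and array on a log2 scale, made by the authors with Partek 6.6 and RMA (robust multi-array averaging, which corrects background, makes the arrays' distributions alike and summarises the probes of a probe set), per the submitters' processing notes. The notes give neither the order of the steps nor the log base, so base 2 rests on RMA's usual output and on the range of the values, and the folds given here depend on it. RMA removes any difference between arrays that is shared by all probe sets. The probes were designed on mouse sequence. Mismatches with hamster RNA can lower a probe set's signal and shrink its difference, so genes were not ranked by level, and a probe set without a difference does not show an unchanged gene. Levels of different probe sets were set against each other only to choose the probe set of a gene, to leave out the dimmer ones, to match random lists and to ask which exceeded the Bacillus controls. A probe set dimmer than these controls may be dim through mismatches and does not show an absent transcript.

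The table held 22690 probe sets. The 64 control probe sets were left out, and 22626 were tested with no filter on level. Gene names came from the platform annotation: 20380 probe sets had 1 gene symbol, 691 had several and 1555 had none there, and no gene was named from a probe set with several. The 20380 probe sets stood for 12393 gene symbols, of which 10256 (82.8%) were also symbols of the RefSeq annotation of the hamster assembly BCM_Maur_2.0. No genome was used, so positions are not given. Symbols follow the mouse annotation throughout.

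The arrays were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes on the deposited log2 values, group as the only term, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the 22626 probe sets. All adjusted p-values of single genes in the text come from this limma fit unless another setting is named, and a probe set was called at an adjusted p under 0.05. Differences are implantation minus interimplantation, given with the standard error (SE) of the fit. For counts of genes and for gene lists, the probe set with the highest mean stood for its gene. The genes at an unadjusted p under 0.05 and at least 1.5-fold were counted as well.

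The design, the gene lists, the rule for named genes and all alternatives but those with the hybridisation controls were fixed before the data were examined. The rule named the 12 genes with the largest increase and the 12 with the largest decrease among the called genes whose groups did not overlap, each by its probe set with the smallest p. It also named up to 4 members of each list with the smallest p, every member called over all probe sets or over its list alone, and Hbegf, Ptgs2, Bmp2, Ihh, Lif, Pgr, Esr1, Actb and Gapdh where measured. Gapdh was not measured by a probe set with a single symbol. The 25 lists were stromal decidualisation, uterine epithelium, EGF family ligands and receptors, progesterone and hedgehog targets, estrogen targets, prostaglandin synthesis and signalling, endothelium, hypoxia and glycolysis, macrophages and myeloid cells, T and NK cells, B and plasma cells, neutrophils, smooth muscle, trophoblast and embryo, erythroid cells, cell cycle, extracellular matrix, proteases and inhibitors, immediate early response, interferon response, WNT, BMP and activin signalling, endoplasmic reticulum stress and secretion, water and ion transport, steroid and retinoid metabolism, and reference genes. Some genes stand in several lists.

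Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists, and again with a correlation estimated for each list. The latter takes its p-values from the few residual degrees of freedom of the arrays, which the former does not. It is therefore stricter even where the estimate is no larger than the preset. Limma's fry, which asks whether the members move on balance in 1 direction and makes no comparison with other genes, was run beside it. List medians were also ranked among 10000 random lists of the same size and mean level.

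The calculation was tested on simulated data of this comparison over 22626 probe sets with 50 changed probe sets per fold size. It called 22% of 1.3-fold, 60% of 1.5-fold, 96% of 2-fold and 100% of 3-fold changes, all with the right sign, and 7 of its 146 calls were unchanged probe sets. In a further simulation over 12393 genes, both lists shifted by 0.3 log2 were called and 0 of the other lists were. Simulated probe sets varied independently, so this does not test list calls where members vary together. The shift was also larger than the median of any list called in the real data. The number of arrays limits the precision of all values.

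The alternatives were the replicate number as a block, leaving out each array, repeated quantile normalization, median centring, a trended and robust variance, array weights, leaving out the dimmer probe sets or those whose identifiers mark several transcripts or genes, the mean of a gene's probe sets, the other list tests and unadjusted p-values. Scaling to the hybridisation controls and a model with their mean level on each array as a covariate, which leaves fewer residual degrees of freedom, were added after seeing the data. These controls (BioB, BioC, BioD and Cre, 18 probe sets) are bacterial and phage RNAs added at hybridisation, so they report the amount of labelled RNA on the array rather than RNA per tissue.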

Results

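The data were 6 arrays of hamster uterus on day 5 of pregnancy, 3 of implantation sites and 3 of interimplantation sites, each with 22626 tested probe sets. Values are log2 RMA signals, and the number of arrays limits their precision. The array medians ran from 4.55 to 4.57. The median level of 27 Bacillus control probe sets, to which no hamster RNA corresponds, was 2.68, and 90.5% of the tested probe sets had a mean above it, but only 4330 exceeded the brightest of these controls (5.79). Across probe sets, which are not independent replicates, arrays of the same group correlated at 0.987 or more, and arrays of different groups at 0.985 to 0.989. The first principal component held 38.3% of the variance and separated the groups, at −14.5 to −11.5 for the implantation arrays and 11.4 to 15.4 for the interimplantation arrays. The following component held 24.2% and set interimplantation array 1 (−20.7) apart from interimplantation arrays 2 and 3 (11.6 and 7.67).

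The comparison asked which transcripts differ between the place where a blastocyst has attached and the uterine wall between such places. At the implantation site, Fst, which encodes the activin antagonist follistatin, was 3.28-fold higher. Of the listed genes, 8 of 34 of the cell cycle rose, and of 22 of endoplasmic reticulum stress and secretion 6 rose and 1 fell, in lists that camera did not call with an estimated correlation (adjusted p = 0.0750 and 0.109). Atp1b1, a subunit of the sodium-potassium pump, fell by 2.00 on the log2 scale by its probe set with the smallest p. Its 5 probe sets ran from −2.00 to 0.0026. Cd24a, a surface glycoprotein of many epithelia, was 3.96-fold lower, and the smooth muscle genes Actg2 and Tagln fell. With limma and Benjamini-Hochberg adjustment, 284 probe sets were higher and 238 lower at the implantation site, for 208 and 196 genes. Their median absolute difference was 0.56, and 37 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 3163 probe sets, where 1131 were expected by chance, and the groups did not overlap in 19.3% of all probe sets, where chance gives 10%. By the probe set with the highest mean, 94 genes were higher and 57 lower at an unadjusted p under 0.05 and at least 1.5-fold.

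The hybridisation controls were dimmer on average on the implantation arrays (6.64 ± 0.17, SD, n = 3) than on the interimplantation arrays (7.03 ± 0.27, SD, n = 3). The groups overlapped, with implantation array 3 at 6.77 and interimplantation array 2 at 6.75, and the difference was not tested. Scaling every array to these controls moved the median difference of all probe sets from −0.02 to 0.38 and the calls from 284 higher and 238 lower to 752 higher and 13 lower. Directions given for the deposited values are therefore relative to the bulk of the probe sets. Because each array is shifted by its own control level, the scaling also brings the controls' spread within the groups into every probe set. A call lost with it is therefore not due to the shift alone. The counts also depended on single arrays: without implantation array 1, 2 or 3 the higher calls numbered 117, 172 and 154, and the lower calls 88, 114 and 98. The lower calls numbered 401 without interimplantation array 1, 136 without array 2 and 125 without array 3. Without the probe sets shared by several transcripts or genes, 138 were higher and 96 lower, and the 94 and 57 genes at an unadjusted p became 60 and 25, or 49 and 27 with the mean of a gene's probe sets and 972 and 10 with the control scaling. With array weights the lower calls numbered 363. In a model with the control level of each array as a covariate, 77 probe sets were higher and 130 lower. The 57 lower genes at an unadjusted p and 1.5-fold became 127 in that model. Both uses of the controls were chosen after seeing the data.

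Fst had the largest increase of the called genes, from 5.33 ± 0.15 between the sites to 7.04 ± 0.32 at the site (SD, n = 3), a difference of 1.71 (SE 0.14, adjusted p = 1.34e-04). Cycs, which encodes the electron carrier cytochrome c, rose by 1.60 (adjusted p = 2.03e-05, from 6.09 ± 0.11 to 7.69 ± 0.18, SD, n = 3), although 1 of its 3 probe sets did not move (−0.05). Hnrnpab, an RNA-binding protein, rose by 1.31 (adjusted p = 1.03e-05), with 6 of its 7 probe sets positive. The chaperone of the endoplasmic reticulum Hyou1 rose 2.47-fold (adjusted p = 0.00121) and Manf, a secreted protein of the same compartment, 2.23-fold (adjusted p = 0.00381). Increases of 2.13-fold to 2.23-fold were seen for Tmsb10, which binds actin monomers, Nppc, the precursor of C-type natriuretic peptide, Nhp2, a protein of small nucleolar ribonucleoproteins, Lrrc59, Ada, which deaminates adenosine, the cytosolic chaperone Hsp90aa1 and Cks2, a binding partner of cyclin-dependent kinases. Of these 7, Lrrc59 had the smallest adjusted p (7.06e-05) and Nhp2 the largest (0.0157). Other probe sets moved less, down to −0.087 for Tmsb10, 0.13 for Hyou1, 0.25 for Lrrc59, 0.41 for Hsp90aa1, 0.45 for Cks2 and 0.53 for Nhp2. The call of Nhp2 was lost with a trended and robust variance (adjusted p = 0.0714) and without implantation array 1, 2 or 3 (adjusted p = 0.0942, 0.0818 and 0.0520). Manf and Nhp2 were not called with the control level as a covariate (adjusted p = 0.101 and 0.284).

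Among the decreases, Atp1b1 fell from 7.54 ± 0.38 to 5.54 ± 0.05 (SD, n = 3; difference −2.00, SE 0.15, adjusted p = 6.57e-05), with 4 of its 5 probe sets negative. Cd24a fell from 6.41 ± 0.04 to 4.42 ± 0.11 (SD, n = 3; difference −1.99, SE 0.09, adjusted p = 6.74e-07). Ogt, the enzyme that attaches N-acetylglucosamine to serine and threonine of intracellular proteins, fell by 1.76 (adjusted p = 2.38e-06), with 4 of its 5 probe sets negative. Actg2, the gamma actin of visceral smooth muscle, fell from 8.03 ± 0.57 to 6.29 ± 0.56 (SD, n = 3; adjusted p = 0.00621) and lost its call with a trended and robust variance (adjusted p = 0.153, the highest of its alternatives) and with the control level as a covariate (adjusted p = 0.0583). Itm2b (−1.35, adjusted p = 5.60e-04), Sat1, which acetylates spermidine and spermine (−1.28, adjusted p = 0.00242), and Tagln, an actin-binding protein of smooth muscle (−1.26, adjusted p = 0.00343), followed. Ivns1abp, the small heat shock gene Hspb1, the histone methyltransferase Kmt5b, Ypel3 and Ypel5 fell 2.00-fold to 2.15-fold. These values come from each gene's probe set with the smallest p, and other probe sets of some genes moved less. The highest of them were at −0.71 for Hspb1, −0.19 for Ivns1abp, −0.13 for Cd24a, −0.074 for Ypel5 and −0.064 for Kmt5b. For Atp1b1, Itm2b and Ogt the highest were positive, at 0.0026, 0.057 and 0.14. With scaling to the hybridisation controls, Ypel3 and Ypel5 were at −0.67 and −0.61 and were no longer called (adjusted p = 0.0541 and 0.0817).

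**Figure D1:**
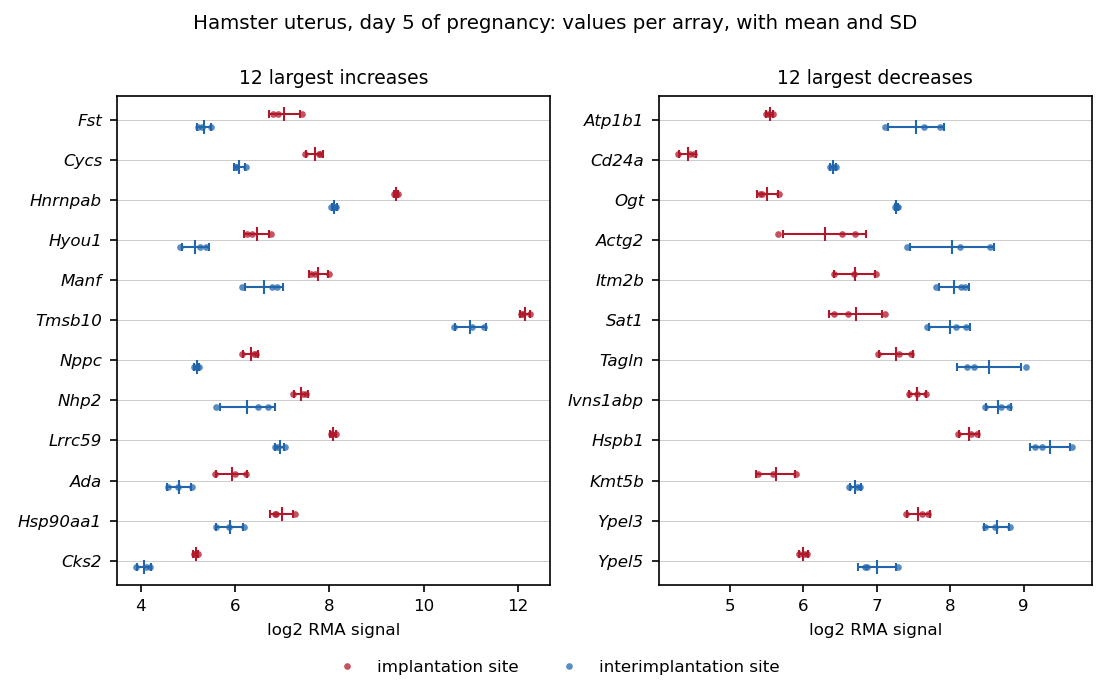
Log2 RMA signal (horizontal axis) of the 12 genes with the largest increase (left) and the 12 with the largest decrease (right) at the implantation site, with each array as a point, the group mean as a tick and the SD as a bar (n = 3). The groups do not overlap for any of these genes, and the SDs of Actg2 (0.56 and 0.57) exceed those of Atp1b1 (0.05 and 0.38).

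Cell cycle genes were higher as a group. Of 34 measured members of the list, 8 rose, 0 fell and 26 did not pass, and 13 rose adjusted over the list alone. The list median was 0.13 (camera adjusted p = 6.18e-10, and adjusted p = 0.0750 with an estimated correlation). Rrm1, a subunit of ribonucleotide reductase, rose by 1.02 (adjusted p = 7.09e-04), Mcm7, of the replicative helicase, by 0.92 (adjusted p = 0.00116), the polymerase clamp Pcna by 0.80 (adjusted p = 0.00179) and Ube2c, a ubiquitin-conjugating enzyme of mitosis, by 0.99 (adjusted p = 0.00441). Cks2, Cks1b (0.50), the mitotic kinase Cdk1 (0.54) and Mcm5 (0.60) were the other members called. Mki67 and Top2a, widely used proliferation markers, were at 0.02 and 0.03 and were not called. Cks1b lost its call without implantation array 1 (adjusted p = 0.0811), Cdk1 without implantation arrays 1 and 3 and interimplantation array 3 (adjusted p = 0.111, 0.0937 and 0.0519), and Mcm5 without any array but interimplantation array 1 (adjusted p from 0.118 to 0.177) and without shared probe sets (adjusted p = 0.0502). With the control level as a covariate the list kept its call (adjusted p = 1.21e-05), but Ube2c, Cks1b and Cdk1 did not (adjusted p from 0.105 to 0.161).

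Genes of endoplasmic reticulum stress and secretion were also higher as a group: 6 of 22 measured members rose, 1 fell and 15 did not pass, with 9 higher and 1 lower adjusted over the list alone. The median was 0.15 (camera adjusted p = 7.49e-07, and adjusted p = 0.109 with an estimated correlation). Besides Manf, the chaperones Hspa5 (0.86, adjusted p = 4.53e-04), Calr (0.75, adjusted p = 0.00310) and Hsp90b1 (0.61, adjusted p = 0.0371) and the disulphide isomerase Pdia6 (0.51) rose, as did Hyou1 by its brightest probe set (0.63). Herpud1, a gene of the degradation of misfolded proteins, fell by 0.43. Pdia6 lost its call without implantation array 1 or 3 (adjusted p = 0.0590 and 0.0544), and Hsp90b1 without implantation arrays 1 and 2 and interimplantation arrays 1 and 3 (adjusted p from 0.0595 to 0.168). Herpud1 lost its call without implantation arrays 1 and 2 and interimplantation arrays 2 and 3 (adjusted p from 0.0561 to 0.157), and lay at −0.031 with scaling to the hybridisation controls (adjusted p = 0.893). The list kept its call with the control level as a covariate (adjusted p = 0.00162), but Manf, Calr, Hsp90b1, Herpud1 and the brightest probe set of Hyou1 did not (adjusted p from 0.0849 to 0.469). On the same arrays the hybridisation controls were on average 0.40 dimmer at the implantation site, with overlap between the groups. With that scaling the medians of the cell cycle and endoplasmic reticulum lists lay 0.15 and 0.17 above that of all probe sets. The scaling raises every difference alike, so these gaps are the same without it and do not test the difference in the controls.

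In the list of hypoxia and glycolysis, 3 of 21 measured members rose and 0 fell, with 6 higher and 1 lower adjusted over the list alone. The median was 0.093 (camera adjusted p = 0.00122, and adjusted p = 0.307 with an estimated correlation), and fry did not pass it (adjusted p = 0.112). Without probe sets shared by several transcripts or genes the median was −0.016 and the call was lost (adjusted p = 0.0524), as it was with the control level as a covariate (median 0.022, adjusted p = 0.200). P4ha1, a collagen prolyl hydroxylase, rose by 0.53 (adjusted p = 0.00584), the glucose transporter Slc2a1 by 0.75 (adjusted p = 0.0295) and the pyruvate kinase Pkm by 0.41 (adjusted p = 0.0253). Slc2a1 lost its call without implantation array 1, 2 or 3 (adjusted p from 0.0619 to 0.157), and Pkm without these and without interimplantation array 2 (adjusted p from 0.0624 to 0.139). None of these 3 genes was called with that covariate (adjusted p from 0.0664 to 0.296).

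In the list of WNT, BMP and activin signalling, 3 of 33 measured members rose and 0 fell, with 7 higher adjusted over the list alone. The median was 0.053 (camera adjusted p = 0.00261, and adjusted p = 0.109 with an estimated correlation), and without the dimmer probe sets the median was 0.0068 and the call was lost (adjusted p = 0.0645). Fst, Wnt4, a WNT ligand of the uterine stroma (0.63, adjusted p = 0.00633), and Id3, a target of BMP signals (0.47, adjusted p = 0.0345), rose. Id3 lost its call without implantation array 1, 2 or 3 or interimplantation array 2 (adjusted p from 0.0631 to 0.163). The list kept its call with the control level as a covariate (median 0.062, adjusted p = 0.0346), but Wnt4 and Id3 did not (adjusted p = 0.138 and 0.311). Lef1, the transcription factor of WNT signals (0.56), and the WNT antagonist Dkk1 (0.35) did not pass (adjusted p = 0.0628 and 0.0667). Both were called with scaling to the hybridisation controls (adjusted p = 0.00103 and 0.0232). Lef1 was also called with the replicate number as a block (adjusted p = 0.0400). Dkk1 was called with repeated quantile normalization (adjusted p = 0.0476) and without interimplantation array 3 (adjusted p = 0.0491). Bmp2, a morphogen of mouse decidua, was at 0.056 (adjusted p = 0.828, 95% interval −0.12 to 0.24).

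Markers of the uterine epithelium were lower as a group: 3 of 25 measured members fell and 0 rose, with 8 lower adjusted over the list alone and 23 of the 25 negative. The median was −0.17 (camera adjusted p = 1.79e-06, and adjusted p = 0.109 with an estimated correlation), which turned to 0.23 with scaling to the hybridisation controls, 0.15 below the median of all probe sets. The tight junction gene Cldn7 fell by 0.78 (adjusted p = 0.00868), the epithelial WNT ligand Wnt7b by 0.50 (adjusted p = 0.0112) and the transcription factor Sox17 by 0.53 (adjusted p = 0.0467). All 3 lost their calls with that scaling (adjusted p = 0.155, 0.644 and 0.564), Wnt7b without implantation array 1 (adjusted p = 0.0768), and Sox17 without any array but implantation array 2 (adjusted p from 0.0641 to 0.174). With the control level as a covariate the list kept its call (median −0.25, adjusted p = 1.73e-04), but none of the 3 genes did (adjusted p from 0.0677 to 0.114). The keratin Krt18 was at −0.47 and did not pass (adjusted p = 0.0866). It was called without interimplantation array 1 (adjusted p = 0.0149), with array weights (adjusted p = 0.0258) and with the covariate (−0.80, adjusted p = 0.0203). The replicate number as a block also gave a call (adjusted p = 0.0182).

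Smooth muscle genes were lower as a group, but not uniformly. Of 21 measured members 3 (Actg2, Tagln and Hspb1) fell and 0 rose, with 6 lower adjusted over the list alone. Of the 21 differences 13 were negative and 8 positive. The median was −0.17 (camera adjusted p = 0.00801, and adjusted p = 0.307 with an estimated correlation), which turned to 0.23 with scaling to the hybridisation controls, 0.15 below the median of all probe sets. Without the shared probe sets the median was −0.029 and the call was lost (adjusted p = 0.291), as it was with the control level as a covariate (median −0.16, adjusted p = 0.0698). Cnn1, calponin of contractile cells, was at −0.39 (adjusted p = 0.0509). It was called with array weights (adjusted p = 0.0418) and without the dimmer probe sets (adjusted p = 0.0347). Myl9 (−0.37), Acta2 (−0.24) and Des (0.13) did not pass, though Myl9 was called without interimplantation array 1 (adjusted p = 0.0324). The smooth muscle myosin Myh11 was at 0.059 by the brighter of its 2 probe sets, which stood for it in the list (adjusted p = 0.836). Its other probe set, chosen after its values were seen, was at −0.85 (adjusted p = 0.00342), and at −0.45 with no call with scaling to the hybridisation controls (adjusted p = 0.129). In the same arrays the difference between the 3′ and 5′ probe sets of actin was 0.35 ± 0.17 at the implantation site and 0.53 ± 0.04 between the sites (SD, n = 3), and that of Gapdh was −0.52 ± 0.05 and −0.57 ± 0.27.

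Immediate early genes, which respond within minutes to growth factors and stress, were lower as a group: 3 of 24 measured members fell and 0 rose, with 1 higher and 6 lower adjusted over the list alone. The median was −0.15 (camera adjusted p = 0.00302, and adjusted p = 0.141 with an estimated correlation), which turned to 0.24 with scaling to the hybridisation controls, 0.13 below the median of all probe sets. Jun fell by 0.89 (adjusted p = 0.00469) and Btg2, an antiproliferative gene, by 0.75 (adjusted p = 0.00547), and both lost their calls with that scaling (adjusted p = 0.119 and 0.176). Jund fell by 0.39 (adjusted p = 0.0290) but was at 0.011 with that scaling, and lost its call without any array but interimplantation array 1 (adjusted p from 0.0868 to 0.147). With the control level as a covariate, the list (median −0.11, adjusted p = 0.0698), Jun (adjusted p = 0.0828) and Jund (adjusted p = 0.115) were not called.

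Genes of stromal decidualisation, the change of uterine stroma into decidua, did not move together: 3 of 29 measured members rose and 1 fell, with 5 higher and 1 lower adjusted over the list alone. The median was 1.0e-05, the mean 0.055 and the test's direction upward (camera adjusted p = 0.480). Gja1, a gap junction connexin, rose by 1.04 and Fkbp4, a cochaperone of the progesterone receptor, by 0.70 (adjusted p = 0.00249 for both), as did Wnt4, while the homeobox gene Dlx5 fell by 0.65 (adjusted p = 0.0264). Dlx5 lost its call without implantation arrays 2 and 3 and interimplantation array 3 (adjusted p = 0.0678, 0.0869 and 0.0907) and with scaling to the hybridisation controls (−0.25, adjusted p = 0.286). Hand2, a stromal transcription factor induced by progesterone, was at 0.58 (adjusted p = 0.0685). It was called without interimplantation array 1 (adjusted p = 0.0493), with array weights (adjusted p = 0.0446), without the dimmer probe sets (adjusted p = 0.0466) and with the control scaling (adjusted p = 7.89e-04). Gja1, Fkbp4 and Wnt4 were not called with the control level as a covariate (adjusted p = 0.0583, 0.0716 and 0.138), nor was Dlx5 (−0.35).

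For the hormones of implantation, the list of progesterone and hedgehog targets had 1 of 21 members higher (Fst) and 0 lower, with 2 higher and 1 lower adjusted over the list alone. Its median was −0.024, its mean 0.080 and its test's direction upward (camera adjusted p = 0.505). Of 22 estrogen targets, 1 rose (Wnt4) and 0 fell, with 2 higher and 1 lower adjusted over the list alone (median 0.012, camera adjusted p = 0.505). The progesterone receptor Pgr was at 0.32 (adjusted p = 0.395), the estrogen receptor Esr1 at 0.041 (adjusted p = 0.884, 95% interval −0.15 to 0.23), the hedgehog ligand Ihh at −0.18 (adjusted p = 0.523) and the cytokine Lif at −0.30 (adjusted p = 0.112). Pgr was called without interimplantation array 1 (0.55, adjusted p = 0.0128) and with scaling to the hybridisation controls (0.72, adjusted p = 0.0320). Of 22 genes of steroid and retinoid metabolism, 1 rose and 0 fell, with 2 higher adjusted over the list alone (median 0.017, camera adjusted p = 0.444). It was Aldh1a2, which makes retinoic acid (0.84, adjusted p = 0.0112), and its call was lost without interimplantation array 3 (adjusted p = 0.0512) and with the control level as a covariate (adjusted p = 0.213), as was that of Wnt4 (adjusted p = 0.138).

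None of the 10 measured EGF family ligands and receptors passed, over all probe sets or adjusted over the list alone (median −0.067, camera adjusted p = 0.505). Hbegf, the ligand that marks attachment in the mouse, was at −0.051 (SE 0.11, adjusted p = 0.884, 95% interval −0.28 to 0.18), with 4.87 ± 0.13 and 4.92 ± 0.17 (SD, n = 3) in the groups. In prostaglandin synthesis and signalling, 0 of 18 members passed, over all probe sets or adjusted over the list alone (median −0.061, camera adjusted p = 0.708). Ptgs2, the inducible cyclooxygenase, was at 0.17 (adjusted p = 0.667, 95% interval −0.14 to 0.49).

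Markers of other cell types gave few calls. Of 25 macrophage and myeloid genes, Cd74 alone fell, also adjusted over the list alone (−0.47, adjusted p = 0.0417; list median −0.089, camera adjusted p = 0.444). It was no longer called without any array but interimplantation array 2 (adjusted p from 0.0640 to 0.166), with scaling to the hybridisation controls (adjusted p = 0.734) or with their level as a covariate (adjusted p = 0.453). Of 25 trophoblast and embryo genes, only Sox17, also an epithelial gene, fell and 0 rose, with 1 lower adjusted over the list alone (median −0.048, camera adjusted p = 0.505). No member passed, over all probe sets or adjusted over the list alone, among 19 endothelial genes (median −0.0032, camera adjusted p = 0.782), 18 of T and NK cells (median −0.043, camera adjusted p = 0.708) and 12 of erythroid cells (median −0.075, camera adjusted p = 0.505). The same held for 9 genes of B and plasma cells, whose median was 0.020 but whose mean was −0.028 (camera upward, adjusted p = 0.993), and for 13 of neutrophils, whose median was −0.013 but whose mean was 0.0046 (camera upward, adjusted p = 0.708). Probe sets shared by several globin or immunoglobulin kappa genes, which name no single gene, stand in none of these lists and were chosen after their values were seen. Those of alpha globin differed by −1.01 and −0.26 (adjusted p = 0.00123 and 0.150), and by −0.61 and 0.14 with scaling to the hybridisation controls (adjusted p = 0.0806 and 0.554). That of beta globin differed by −0.48 (adjusted p = 0.0104), and by −0.080 with that scaling (adjusted p = 0.724). Those of the kappa chain differed by −1.13, −1.12 and −0.31 (adjusted p = 0.00540, 0.00308 and 0.179), and by −0.73, −0.72 and 0.083 with that scaling (adjusted p = 0.0295, 0.0327 and 0.717).

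Of the remaining lists, extracellular matrix (0 of 26 members, median 0.0019, camera adjusted p = 0.505) and interferon response (0 of 22 members, median −0.085, camera adjusted p = 0.444) had no call, and none adjusted over the list alone. Of 23 proteases and inhibitors, the lysosomal protease Ctsb fell by 0.43 (adjusted p = 0.0467), with 2 lower adjusted over the list alone (median −0.018, camera adjusted p = 0.897), and it lost its call without any array but interimplantation array 1 (adjusted p from 0.0778 to 0.224), without shared probe sets (adjusted p = 0.0561) and with scaling to the hybridisation controls (adjusted p = 0.869). Of 22 genes of water and ion transport, Atp1b1 fell, by 0.68 by its brightest probe set (with the control scaling −0.28, adjusted p = 0.250, and with the covariate −0.42, adjusted p = 0.196), and 1 was lower adjusted over the list alone. The median of this list was −0.13 (camera adjusted p = 0.0803, fry adjusted p = 0.00579) and turned to 0.26 with scaling to the hybridisation controls, 0.11 below the median of all probe sets. Camera called the list without interimplantation array 2 (adjusted p = 0.0491). Of 14 reference genes, the tubulin Tubb5 rose by 0.92 (adjusted p = 0.00751), with 2 higher adjusted over the list alone, and Actb was at 0.23 (adjusted p = 0.464). Tubb5 lost its call without implantation array 1 or 2 (adjusted p = 0.0501 and 0.0511) and with the covariate (adjusted p = 0.177). The reference median was −0.0040, the mean 0.057 and the camera direction upward (adjusted p = 0.577). None of the 25 lists passed camera with an estimated correlation, while fry passed 7, namely the lists called by camera other than hypoxia and glycolysis, and water and ion transport. The estimate was close to the preset 0.01 for the cell cycle (0.013) and immediate early (0.010) lists, and −0.024 for WNT, BMP and activin signalling. A stronger correlation among members therefore hardly accounts for the lost calls of these lists. Camera with an estimated correlation has far fewer degrees of freedom, which alone raises p. For WNT, BMP and activin signalling the unadjusted camera p went from 5.23e-04 to 0.0163, although the estimate lay below the preset. The lost calls of these lists are thus no evidence of members that vary together. For the other called lists the estimates ran from 0.049 to 0.13.

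**Figure D2:**
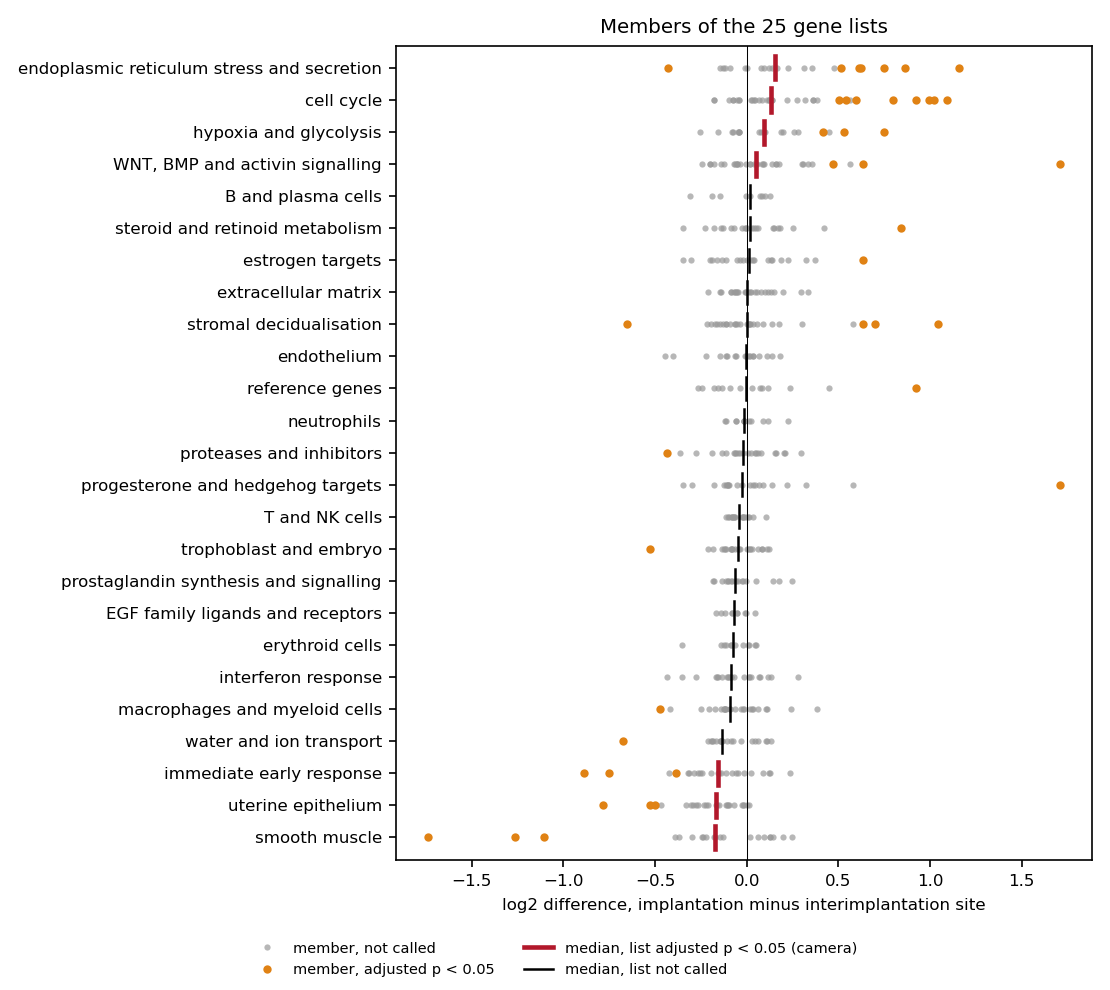
Log2 difference between implantation and interimplantation sites (horizontal axis) of each measured member of the 25 gene lists (vertical axis, ordered by median), with called members in orange and the medians of the 7 called lists in red. The medians of the endoplasmic reticulum (0.15) and cell cycle (0.13) lists lie highest, and those of the smooth muscle (−0.17), uterine epithelium (−0.17) and immediate early (−0.15) lists lie lowest. Scaling to the hybridisation controls raises every difference by 0.40, so the medians of all 25 lists are positive with it. The lowest 3 then still lie 0.13 to 0.15 below the median of all probe sets.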

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

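Scaling to the hybridisation controls and their level as a covariate were chosen after seeing the data, and the other alternatives before. Of the 56 called named probe sets, 37 kept their call in every other alternative that held them. Only 32 of the 56 remained without shared probe sets and 53 without the dimmer ones, and those left out were not tested there. Under the scaling 43 kept it, 12 lost it and Jund turned to 0.011, and with the covariate 29 kept it and 27 lost it. Of the 7 called lists, 4 kept their call in every alternative but these and the estimated correlation. All 56 kept it with array weights, repeated quantile normalization, median centring and the replicate block, 54 with a trended and robust variance, 30 of 32 without shared probe sets and 40 to 53 when an array was left out. The 284 higher probe sets became 138 without shared probe sets (15605 left), 752 with the hybridisation controls, 77 with the covariate and 1273 at an unadjusted p, and 117 to 329 when an array was left out. The 238 lower ones became 96, 13, 130 and 1890 in these settings and 363 with array weights, and 88 to 401 when an array was left out. Calls after leaving out shared probe sets were 234, all of them among the 522. The 94 higher genes at an unadjusted p and 1.5-fold became 60 without shared probe sets, 49 with the mean of a gene's probe sets and 972 with the hybridisation controls (83 to 106 when an array was left out). The 57 lower genes became 25, 27 and 10 (46 to 84), and 127 with the covariate. The 7 lists became 0 with an estimated correlation and 4 with the covariate, and stayed at 7 to 8 when an array was left out. With the hybridisation controls the medians of the epithelium, smooth muscle and immediate early lists turned to 0.23, 0.23 and 0.24, while that of all probe sets was 0.38. Without shared probe sets the median of the hypoxia list turned to −0.016. The median of genes with the prefix Eif turned to −0.0038 without interimplantation array 1 (highest without another array 0.033) and to −0.023 without shared probe sets. The cause was not tested. Fewer arrays or probe sets entered where some were left out, and the covariate and the estimated correlation leave fewer degrees of freedom. The control scaling raises every difference by 0.40. It also brings the spread of the controls within the groups (SD 0.17 and 0.27) into every probe set, so a call can be lost through either. Signal over background may limit the rest, which was not tested: 4330 probe sets lay above the brightest Bacillus control, and 90.5% of all tested ones above the median of these controls.

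With the replicate number as a block (replicate block), 294 probe sets were higher and 240 lower, and 463 of these calls were among the 522. The list calls stayed at 7, and of the 93 named probe sets not called 6 were called, namely Krt18, Zfp36, Stra6, Lef1, Usp18 and P4ha2 (adjusted p from 0.0182 to 0.0487). The deviations of same-numbered arrays from their group means correlated at −0.090, 0.071 and −0.028, and those of other pairs at −0.093 to 0.10. Only the arrays numbered 2 correlated best with their own number, so the numbers were not taken to pair the samples.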

Other observations

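The tests here were chosen after the results they bear on were seen, and so were the genes and families named first. Exceptions were camera with an estimated correlation on the 25 lists and the count of genes in other splits of the 6 arrays, which were planned. Genes were grouped by the letters before the number of their symbols, and 210 such families of at least 8 genes were tested with camera. At the implantation site 8 families passed, all upward, and 0 passed with an estimated correlation, where camera has fewer degrees of freedom (adjusted p from 0.605 to 0.846). The subunits of the cytosolic chaperonin (Cct) had the largest median, 0.59, with 5 of 8 genes called higher (camera adjusted p = 3.25e-06). Proteasome subunits had medians of 0.27 for Psma (2 of 8 called higher, adjusted p = 2.75e-05), 0.30 for Psmd (3 of 14, adjusted p = 1.27e-04) and 0.10 for Psmb (3 of 10, adjusted p = 0.0143). Psmb lost its call without interimplantation array 1 (adjusted p = 0.0642). Mitochondrial ribosomal proteins of the large subunit (Mrpl, 0.10, 1 of 47 called higher, adjusted p = 4.22e-04), mitochondrial import proteins (Timm, 0.15, 2 of 14, adjusted p = 6.67e-04) and nucleoporins (Nup, 0.11, 3 of 16, adjusted p = 7.06e-04) passed as well. Those of the small mitochondrial ribosomal subunit did not pass (Mrps, 0.017, 2 of 27, adjusted p = 0.149). Genes with the prefix Eif (median 0.0084, adjusted p = 0.0146), mostly translation initiation factors, went both ways, with 6 of 42 higher and 2 lower. Of the 2 lower, Eif2ak4 (−0.52) is a kinase rather than an initiation factor. The median of this family turned to −0.0038 without interimplantation array 1 and to −0.023 without shared probe sets. The call was lost without shared probe sets and with repeated quantile normalization (adjusted p = 0.305 and 0.0618). With the control level of each array as a covariate, Cct alone of the 8 families was called (median 0.31, adjusted p = 0.0166), with 4 of its 5 called genes no longer called. The other 7 were not called (adjusted p from 0.0881 to 0.623). Eif4a1 rose by 0.95 and Eif4a2, a close paralog, fell by 0.60 (adjusted p = 0.00121 and 0.00917), the latter without a call when implantation array 3 was left out (adjusted p = 0.0553) or arrays were scaled to the hybridisation controls (−0.20, adjusted p = 0.387), or with that covariate (adjusted p = 0.0623).

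Among the genes that fell, the autophagy genes Map1lc3b and Gabarap were at −0.79 and −0.78 (adjusted p = 0.00108 and 0.00547). The splicing kinase Clk1 was at −0.82 (adjusted p = 0.00335) and the transcription factor Klf9 at −0.69 (adjusted p = 0.00189). With scaling to the hybridisation controls these 4 stayed negative, at −0.42 to −0.29, and were not called (adjusted p from 0.138 to 0.235). Klf9 was not called with the covariate (adjusted p = 0.0583). All 4 values come from the gene's probe set with the smallest p. Other probe sets ran up to 0.026 for Map1lc3b (3 of 4 negative) and 0.030 for Klf9 (6 of 7 negative). Hnrnpa2b1 was the 1 gene called in both directions, with 0.74 by 1 probe set and −0.39 by another (adjusted p = 0.00897 and 0.0323). Scaling to the hybridisation controls raises every difference by 0.40, so the negative one barely turned positive and the gap between both stayed the same. The positive one was not called with the covariate (adjusted p = 0.161).

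The implantation split of the 6 arrays gave 522 called probe sets against at most 0 in the other splits, 151 genes at an unadjusted p and 1.5-fold against at most 19, and 7 lists against at most 2. In each case 1 of the 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05.

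The chaperone and cell cycle lists were higher at the implantation site, where the hybridisation controls were dimmer on average. With each array's control level in the model, both kept their calls by camera at the preset correlation (larger adjusted p = 0.00162). Their medians did not shrink, at 0.17 and 0.18 against 0.15 and 0.13 without it. That camera p takes no account of the few degrees of freedom left. The control level itself also differed between the groups, so brightness was left open as a cause. Without that term neither list was called with an estimated correlation (adjusted p = 0.109 and 0.0750). The hypoxia list (0.022, adjusted p = 0.200), the smooth muscle list and the immediate early list (adjusted p = 0.0698 for both) lost their calls with the control level in the model. Among random lists of the same size and mean level, the cell cycle median stood at percentile 100 and the chaperone median at percentile 99.99, which argues against normalization by brightness. RNA of embryo cells in the sampled site stays open: 0 of 25 trophoblast and embryo members were called higher, but only 5 of them were brighter than the brightest Bacillus control. A response of the uterus to the blastocyst may also be the cause and was not tested apart from the embryo's own RNA.

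For the fall of smooth muscle genes, a smaller share of uterine muscle in the implantation samples may be the cause. The 9 members brighter than every Bacillus control differed by −1.74 to 0.20 (SD 0.68, median SE 0.13), so they did not fall by a common amount, but the response of mouse probes to each hamster transcript is unknown and the explanation stays open. Of 2 genes with 3′ and 5′ probe sets, 1 separated the groups: the 3′ minus 5′ difference of actin was lower at the implantation site (0.35 against 0.53), opposite to stronger degradation there, while Gapdh did not separate them, and a difference in degradation between the groups was left open. Lower transcription in the muscle of the site was not tested. With the control level in the model, the list was no longer called (adjusted p = 0.0698), and its median was −0.16 against −0.17 before, in a model with 1 more term.

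Interimplantation arrays 2 and 3 stood apart from the other 4 in a small set of probe sets, and the B1 repeat probe set was at 6.21 and 5.53 in them against 7.46 to 7.57 in the others, 1 B2 repeat probe set at 6.64 and 6.63 against 7.58 to 7.74, and another at 4.80 and 5.03 against 5.12 to 5.15. In 14 probe sets both lay at least 0.5 below all 4 others, against at most 1 for any other of the 15 pairs, and in 12 at least 0.5 above, again against at most 1, and 15 pairs are too few for a share under 0.05. A Zbtb20 probe set was at 4.93 and 4.85 in these arrays, 6.54 to 7.05 in the implantation arrays and 8.55 in interimplantation array 1, which thus stood apart as well, and another of its 3 probe sets had SDs of only 0.04 and 0.10 in the groups. In the 3′ minus 5′ difference, 1 of 2 genes, Gapdh, put both arrays outside the other 4, but lower (−0.71 and −0.73 against −0.55 to −0.26), opposite to stronger degradation in these arrays, and actin did not, so degradation in some arrays was left open. No biological explanation was tested, as the labels give no difference between these animals.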
